A study of Mus musculus with 2 samples.

How the data were processed

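RNA-seq of sorted LSK cells was analysed from 2 libraries, 1 of p53 KO and 1 of Utx/p53 DKO mice of the C57BL/6 strain, grouped by the genotype in the labels. Per the labels' protocols, cells were sorted into a lysis reagent, 50 ng of total RNA was reverse transcribed and amplified with a SMART cDNA kit after oligo-dT selection, and libraries were sequenced from both ends at 100 bases. SMART amplification and PCR without molecular identifiers can distort low values. The strandedness of the counting is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.1.0 and the mouse build mm9.

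The 1 table used holds 28344 RefSeq transcripts of 22020 gene symbols and was made with gfold 1.1.4, per the file headers. The authors deposited RPKM values (reads scaled by transcript length and by the read total) of both libraries, in a first and a second RPKM column. The file's header lists the library WT-LSK first (the p53 KO mouse cells) and KO-LSK second (the DKO cells), matched to the samples by their titles. Columns were assigned by that order, and each gave whole reads with the read total of its library. The authors' deposited table also gives a log2 fold change and the GFOLD value on a log2 scale, and a q-value (E-FDR), which was 1 for every transcript. Per the file headers, gfold used 17088105 and 19926294 reads and normalization constants of 1.30144 and 1. Checked on the values, RPKM was scaled by the read totals alone, and the authors' log2 fold change was that of reads with 1 added and the constants applied, so both scales differ by 0.602 on the log2 scale. How reads mapping to several places were counted is not given in the sources used here.

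The genes were compared on log2(RPKM + 1), which understates the change of low genes, using for each symbol the transcript with the highest mean and keeping the 11356 genes with a mean of at least 1 RPKM over both libraries. With 1 library per genotype no test was made and no p-value computed here. A gene counted as higher or lower at a difference of at least 2-fold on that scale. Gene lists (29, with 732 members of which 722 were found and 592 measured) and the chromosomes were described by the median of their log2 ratios, its distance from the median of all genes, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5, and 10 of the 29 lists lay below and 6 above. About 1.45 lists would do so if all genes varied independently. Genes of 1 list can vary together between any 2 libraries, so that number is no measure of chance for these lists. Some genes stand in more than 1 list. Chromosome and gene order came from the GRCm38.p6 RefSeq table by transcript accession, which placed 11279 (99.3%) of the measured genes; no coordinates are given because the build differs from mm9.

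Whole reads were recovered from the RPKM values by searching, for each transcript, the whole-number length at which both values are whole reads within the rounding of the printed digits and match the authors' log2 fold change. Exactly 1 solution was found for 96.5% of the 24644 transcripts with reads and no solution for 0%. The measured genes with recovered reads (10914, 96.1%) had a median of 435 reads in the p53 KO and 419 in the DKO library. The reads gave exact (Clopper-Pearson) 95% intervals of the RPKM ratio and a floor of 3 reads for a gene at 0. These cover counting error only. A count test across genes was not made, because 2 libraries without replicates would be compared rather than genotypes. On simulated data the recovery gave 1 solution for 92.3% of 1485 transcripts, all of them correct, and the percentile placed 2 to 4% of unshifted lists above its upper bound. Lists of 5, 12 and 30 genes were found in 50, 80 and 100% of draws at a shift of 1 on the log2 scale and in 23, 30 and 58% at a shift of 0.5. The simulated genes varied independently, unlike genes of a cell type.

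Before the data were examined, these choices were fixed: the gene lists, the size rule, the filter and the genes to name, which were Kdm6a, Trp53, the 12 genes with the largest increase and the 12 with the largest decrease (predicted, clone and small RNA names left out), up to 4 members per list with the largest absolute log2 ratio, and all sex-linked genes. Genes named beyond that rule were chosen after their values were seen: further members of the granulocyte, T and NK cell, macrophage and endothelial lists, Ly6a, the olfactory and vomeronasal receptor genes, and all genes and families named only in the closing part. The point that divides chromosome 2 was also placed after its values were seen. Alternatives fixed then were pseudocounts of 0.1 and 5, no filter, a mean of at least 5, centring on the median of the genes with that mean, scaling to equal totals or upper quartiles, 3-fold and 1.5-fold rules, 10 bins, list means in place of medians, and a stricter q-value of 0.01. Chosen after seeing the data were the authors' gfold constants, means over the transcripts of a symbol, random lists also matched on transcript length, lists without near-identical copies, and leaving out the distal genes of chromosome 2. The GC content of Gencode M21 transcripts, matched by accession, served for that chromosome. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.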

Results

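RNA from haematopoietic stem and progenitor cells of 8-week-old mice was sequenced to compare gene expression between 2 genotypes that both lack p53. The cells were LSK cells, a sorted fraction without lineage markers and with the surface proteins c-Kit and Sca-1, which holds the stem cells and the earliest multipotent progenitors of the blood. In the p53 KO mice the gene for the tumour suppressor p53 (Trp53) was deleted, and in the Utx/p53 double knockout (DKO) mice Kdm6a (Utx), an X-linked gene for a histone H3 lysine 27 demethylase, was deleted as well. There was 1 library per genotype, with 17088105 reads (p53 KO) and 19926294 reads (DKO) given in the file's header. No difference below has a replicate check: every value describes these 2 libraries, and the spread between mice is unknown. Intervals cover counting error only.

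Of the targeted genes, Kdm6a was lower in the DKO library, at 5.32 against 1.26 RPKM (479 against 132 reads; p53 KO first here and below). Its RPKM ratio, DKO over p53 KO, was 0.236 (95% interval 0.193 to 0.287), and its log2(RPKM + 1) difference was -1.49. Trp53 transcripts were present in both libraries, at 19.4 against 12.9 RPKM, a log2 difference of -0.55 whose sign depended on the scaling (0.01501 with the authors' gfold constants). Over the alternative settings the log2 difference of Kdm6a lay between -2.09 and -0.72. The labels do not give the deleted exons, so whole-transcript values cannot show whether the remaining reads came from the retained part of an allele or from undeleted cells. The other X-linked genes with a Y partner differed less than Kdm6a: Ddx3x was at 59 against 54.7, Eif2s3x at 25.9 against 25 and Kdm5c at 15 against 10.1 RPKM.

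Across the 11356 genes with a mean of at least 1 RPKM, the DKO library held a small set of very abundant transcripts. On the RPKM scale most other genes had lower values in it, but not with the authors' gfold constants (median log2 ratio 0.28). The 10 most abundant genes took 8.17% of the summed RPKM in the p53 KO library and 20% in the DKO library, and the median log2 ratio over all genes was -0.24. By the rule of at least 2-fold on log2(RPKM + 1), 750 genes were higher and 1528 lower in the DKO library, so 32.9% of the called genes were higher. That split depended on the scaling: 1012 higher and 1086 lower after centring on the median of the genes with a mean of at least 5 RPKM (48.2% higher), 943 and 1225 with upper-quartile scaling (43.5%), 577 and 3332 with scaling to equal totals (14.8%), and 1873 and 712 with the authors' gfold constants (72.5%). Those scalings moved the all-gene median by 0.18, 0.13, -0.37 and 0.52, so gene groups are described below by the median of their log2 ratios relative to the median of all genes. Each group's percentile is its place among 10000 random lists matched on expression. Counts of members at least 2-fold higher or lower are not relative to that median unless stated, so they depend on the scaling. Relative to it, 12 rather than 16 of 27 long-term stem cell genes were lower. Likewise, 10 rather than 6 of 24 glycolysis and hypoxia genes were higher. The p53 KO library also had more genes with a few reads: 551 of 1460 olfactory and vomeronasal receptor genes, which blood cells are not known to use and which were chosen after their values were seen, had reads in it, against 128 in the DKO library.

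**Figure D1:**
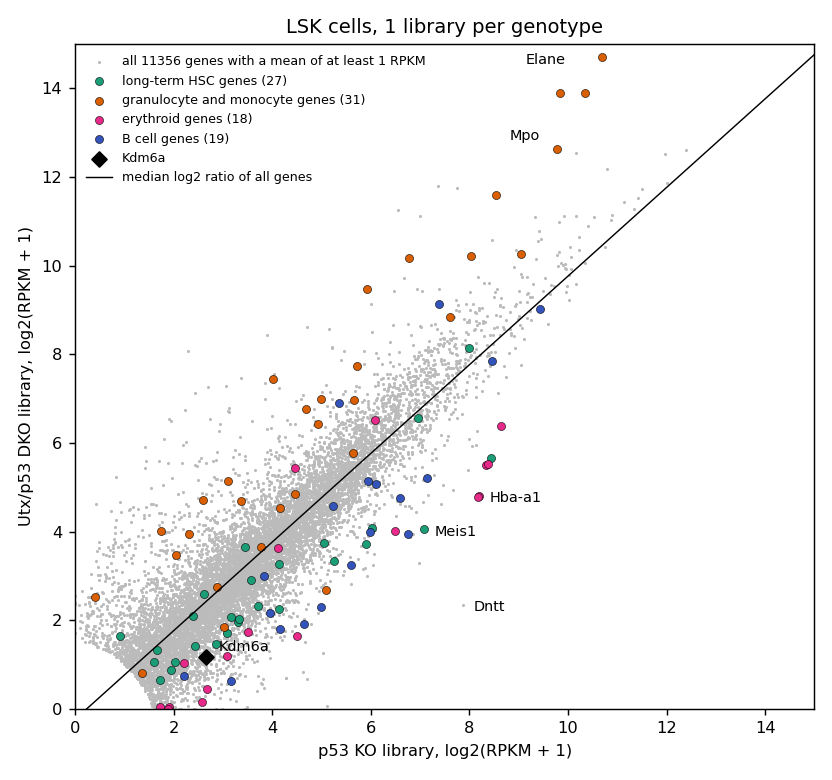
Expression of 11356 genes in the p53 KO library (x axis) and the Utx/p53 DKO library (y axis), both as log2(RPKM + 1), with 1 point per gene and 4 fixed gene lists in colour. The line marks the median log2 ratio of -0.24; granulocyte and monocyte genes such as Elane lie above it and most erythroid, B cell and long-term HSC genes below it.

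The 12 named genes with the largest increase were Ly6i, Chi3l3, Clu, Thbs4, Ly6k, F7, Tmem178, Orm1, Hp, Prps1l1, Mogat2 and C3. Ly6i, of the Ly6 surface protein family, was 69.5-fold higher (95% interval 53.7 to 91.7), at 3.87 against 269 RPKM. Chi3l3, a chitinase-like protein of myeloid cells, was at 92.7 against 2452 RPKM, and Clu, which encodes the secreted chaperone clusterin, at 4.40 against 139. Plasma proteins of the acute phase were among the 12: Hp (haptoglobin) was 21.9-fold higher (95% interval 21.2 to 22.6), at 163 against 3562 RPKM, Orm1 was at 1.68 against 59.4 and complement C3 at 7.38 against 154. Thbs4 was at 2.72 against 92.7, Ly6k at 5.45 against 153, coagulation factor F7 at 2.86 against 89.6, Tmem178 at 3.66 against 107, Mogat2 at 2.48 against 66.7 and Prps1l1 at 0.768 against 36.3 RPKM. Members of the Ly6 and chitinase-like families share sequence, so their reads may be split between copies.

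Dntt, which encodes the terminal transferase of lymphoid progenitors, showed the largest decrease on the log2(RPKM + 1) scale: it was 57.7-fold lower (95% interval 49.5 to 67.7), at 234 against 4.05 RPKM. Rag2, part of the recombinase of lymphocyte receptor genes, had 596 reads in the p53 KO library and 2 in the DKO library (347-fold lower, 95% interval 95.8 to 2876). The basophil protease gene Prss34 had 698 reads against 1 (814-fold lower, 95% interval 146 to 32194), and the eosinophil ribonuclease gene Ear1 had 120 reads against 0, at least 46.6-fold lower with the DKO value set at a floor of 3 reads and 37.4-fold at the lower bound of the exact 95% interval. Siglech, a marker of plasmacytoid dendritic cells, was at 25.2 against 0.586 RPKM, the transcriptional coregulator gene Mn1 at 23.6 against 0.786, and H2-Ob, a modulator of class II antigen loading, at 31.8 against 1.41. The others of the 12 were Hist1h2bg (125 against 8.73), the alpha globins Hba-a1 (290.4 against 26.7) and Hba-a2 (289 against 26.5), Cox6a2 (13.3 against 0.381) and Emp1 (11.9 against 0.314). Ear1, the histone genes and the globins have near-identical copies and their values are uncertain.

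Granulocyte and monocyte genes were higher in the DKO library as a group. Of 31 measured members, 23 were at least 2-fold higher and 2 at least 2-fold lower, the relative median was 2.23 and no random list reached it (percentile 100). Their share of the summed RPKM was 1.85% in the p53 KO library and 15.5% in the DKO library. Elane, the neutrophil elastase of primary granules, was at 1649 against 26714 RPKM, Ly6c2 at 919.5 against 15136, lysozyme Lyz2 at 1302 against 15319 and the siderophore-binding protein Lcn2 at 59.5 against 704 RPKM. Further members, named after their values were seen, included the granule proteins Mpo (876 against 6386), Prtn3 (370.2 against 3080.2) and Ctsg (108 against 1160.4), the transcription factors Cebpa (2.35 against 15.1), Cebpe (5.01 against 25.4) and Gfi1 (3.97 against 14.4), and the receptors Csf1r (7.61 against 34.3) and Fcgr3 (15.2 against 173). The members at least 2-fold lower were Ltf, a secondary granule protein, at 32.9 against 5.42 RPKM, and the integrin Itgam at 7.10 against 2.62 RPKM. Ly6c2 and Lyz2 have close copies and are uncertain.

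The list of long-term haematopoietic stem cell genes was lower in the DKO library: of 27 measured members, 0 were at least 2-fold higher and 16 at least 2-fold lower (relative median -0.85, percentile 0). Meis1, a homeobox factor of stem cells, was 8.59-fold lower (95% interval 8.05 to 9.17), at 134 against 15.7 RPKM. Cd34, a list member not particular to long-term stem cells, was at 348 against 49.1 RPKM. The list also holds both genes of the sort gate, which all LSK cells passed, so its median does not single out long-term stem cells. The genes of the sort gate moved apart: Kit was 4.01-fold lower (95% interval 3.79 to 4.24), at 64.2 against 16 RPKM, while Ly6a, which encodes Sca-1 and is named after its value was seen, was at 255 against 281 RPKM. Of 10 measured Hoxa, Hoxb and cofactor genes, 1 was at least 2-fold higher and 7 were at least 2-fold lower (median -0.99, percentile 0.09). Hoxa7 was at 6.33 against 0.720 and Hoxa9 at 2.34 against 0.221 RPKM, while Pbx3 was higher, at 2.05 against 10.3 RPKM. That group's percentile was 24.3 without the filter on low values. Factors of the GATA and megakaryocyte-erythroid network lay within the range of random lists (median -0.32, percentile 5.71, 12 measured; percentile 2.19 without distal chromosome 2 genes): Gata1 was at 10.4 against 2.31 and Gfi1b at 7.91 against 3.20, but Runx1 was at 8.57 against 20.8 RPKM. So did ETS factors (median -0.20, percentile 18.5, 17 measured), of which Spib (9.94 against 0.666) and Erg (15.9 against 5.08) were lower.

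Erythroid genes had the lowest median of all groups. Of 18 measured members, 0 were at least 2-fold higher and 15 at least 2-fold lower (relative median -1.82, percentile 0), and the beta globins Hbb-b1 and Hbb-b2 were at 324 against 43.9 and 332 against 44.9 RPKM. The list of mast cell, basophil and eosinophil genes was also lower (2 higher and 9 lower of 13, median -1.27, percentile 0), with the IgE receptor gene Fcer1a at 6.73 against 0.293 RPKM, although the granule protease gene Gzmb was higher, at 3.55 against 28.6 RPKM. With the filter at a mean of 5 RPKM the percentile of this list was 43.1. Megakaryocyte genes went both ways (1 higher and 3 lower of 12, median -0.08, percentile 31.4): the integrin gene Itga2b was at 7.54 against 0.949 and Gp9 at 8.23 against 1.11, while P-selectin (Selp) was at 5.75 against 32.2 RPKM.

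Genes of lymphoid progenitors and B cells were lower, and T and NK cell genes went both ways with a higher median. Of 19 measured lymphoid progenitor genes, 0 were at least 2-fold higher and 12 at least 2-fold lower (median -1.07, percentile 0), with the receptor tyrosine kinase gene Flt3 at 24.5 against 1.83 and the TNF receptor family gene Cd27 at 110.0 against 13.8 RPKM. Among 19 B cell genes, 2 were at least 2-fold higher and 12 at least 2-fold lower (median -1.56, percentile 0). Cd79a, part of the B cell receptor complex, was at 106 against 14.4, Blnk at 30.8 against 3.95 and the transcription factor Ebf1 at 8 against 0.536 RPKM. T and NK cell genes lay above the random range (median 0.49, percentile 99.8; 7 higher, 4 lower and 10 within 2-fold of 21). The members at least 2-fold higher were Gzma (2.47 against 12.7), Ncr1 (2.60 against 9.40), Klrd1 (5.22 against 16.8), Klrb1c (4.2 against 10.9), Il2rb (7.36 against 20.9), Cd3d (4.31 against 16.2) and Cd3g (8.07 against 20.2), of which Gzma, Ncr1, Klrd1, Klrb1c and Il2rb are used by NK cells. Lower were the T cell genes Lat (26 against 7.40), Cd4 (2.25 against 0.195) and Gata3 (5.62 against 1.89) and the granule protein gene Nkg7 (229 against 99.6), which NK cells also use.

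Macrophage and dendritic cell genes went both ways, and few endothelial or stromal genes were measured. As 1 list the macrophage and dendritic cell genes lay within the random range (median -0.15, percentile 32.1): of 15 measured, 5 were at least 2-fold higher, Vcam1 (2.45 against 32.2), Slc40a1 (2.39 against 17.6), Emr1 (0.739 against 4.72), C1qb (7.78 against 28.6) and C1qc (5.72 against 12.8), 2 were lower, Siglech and Flt3, and 8 differed by less than 2-fold. With the filter at a mean of 5 RPKM the percentile of this list was 99.7. Only 7 of 23 endothelial and stromal genes in the table reached a mean of 1 RPKM. Of these, 4 were higher, Vcam1, Pecam1 (16.1 against 49.4), Flt1 (1.1 against 13.1) and Acta2 (0.164 against 2.51), and Emcn was lower, at 10.4 against 2.65 RPKM (median 1.8, percentile 100). Vcam1 and Pecam1 are also used by blood cells.

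**Figure D2:**
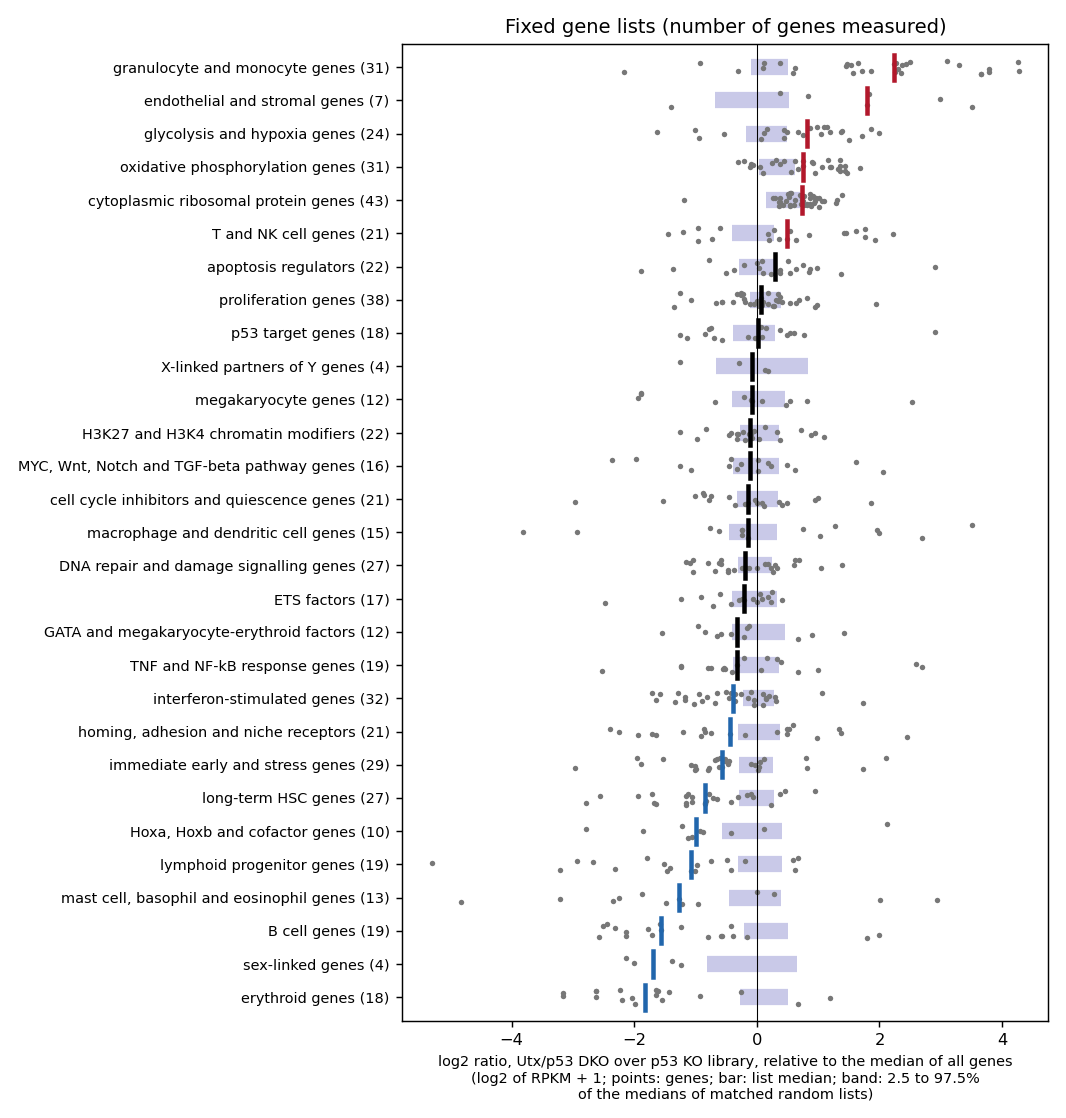
Log2 ratios of the measured genes of 29 fixed lists (x axis; DKO over p53 KO library, log2(RPKM + 1), relative to the median of all genes), with 1 point per gene, a bar at each list's median and a band for the central 95% of the medians of matched random lists. The median of granulocyte and monocyte genes was 2.23 and that of erythroid genes -1.82.

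Genes of energy metabolism were higher relative to all genes. Glycolysis and hypoxia genes had a relative median of 0.81 (percentile 99.96; 6 higher and 3 lower of 24): Eno1 was at 127 against 396, Gpi1 at 65.7 against 186 and the prolyl hydroxylase gene Egln3 at 3.81 against 15.2, while the glucose transporter gene Slc2a3 was at 15.3 against 3.50 RPKM. Oxidative phosphorylation genes had a median of 0.76 (percentile 99.7; 8 higher and 0 lower of 31), with Ndufb3 at 68.6 against 188 and Cox4i1 at 335 against 775 RPKM. Cytoplasmic ribosomal protein genes had a median of 0.74 (percentile 99; 3 higher and 1 lower of 43). Rpl32 was at 481 against 1006 and Rpl13 at 30.6 against 69.3 RPKM, and Rps27 was lower, at 38.2 against 13.6 RPKM. Many of these transcripts are short, and the 2183 genes with the shortest transcripts had a relative median of 0.33. Against random lists also matched on length, ribosomal protein genes no longer stood apart (percentile 93.3). Random lists matched on expression also lay above the all-gene median. Their middle values were 0.14 for glycolysis and hypoxia, 0.31 for oxidative phosphorylation and 0.40 for ribosomal protein genes. Part of each group's median was therefore shared with other genes of that abundance.

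Immediate early and interferon-stimulated genes were lower, and TNF and NF-kB response genes went both ways. Of 29 immediate early and stress genes, 2 were at least 2-fold higher and 10 at least 2-fold lower (median -0.56, percentile 0.02): the nuclear receptor gene Nr4a1 was 26-fold lower (95% interval 17.3 to 41), at 12.7 against 0.486 RPKM, the phosphatase gene Dusp2 was at 38.6 against 7.63 and Zfp36 at 265 against 59.8, while Gadd45b was higher, at 6.79 against 27.4 RPKM. Interferon-stimulated genes were lower as a group (1 higher and 11 lower of 32, median -0.39, percentile 0.09), among them Ifi44 (22.5 against 5.07), Rtp4 (66 against 17.1) and Oasl2 (28.7 against 7.41). The TNF and NF-kB list lay within the range of random lists (median -0.32, percentile 5.05, 19 measured; percentile 2.31 with length matching): the chemokine gene Ccl4 was at 47.2 against 6.08, but Ccl5 was at 41.2 against 232 and Cxcl10 at 5.56 against 32.7 RPKM. Homing, adhesion and niche receptors had a median of -0.44 (percentile 0.37; 3 higher and 9 lower of 21), with the egress receptor gene S1pr1 at 7.36 against 0.348, Ccr7 at 7.97 against 0.610 and the integrin gene Itgb2 at 18.7 against 90.3 RPKM. This group did not stand apart with the filter at a mean of 5 RPKM (percentile 19.1), with no filter (13.4) or without distal chromosome 2 genes (25.4).

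Cell cycle, p53 target and chromatin genes lay within the range of random lists, and apoptosis and DNA repair genes did so in part of the settings. Proliferation genes had a relative median of 0.07 (38 measured, percentile 28.5); Cdk6 was higher, at 17.4 against 58.7, and the D-type cyclins Ccnd1 (15.2 against 5.53) and Ccnd2 (129.5 against 42.5) were lower. Cell cycle inhibitors and quiescence genes had a median of -0.14 (percentile 18.6, 21 measured), with Klf2 at 10.2 against 3.70. In the list of MYC, Wnt, Notch and TGF-beta pathway genes (median -0.12, percentile 28.3, 16 measured), Myc was 4.75-fold lower (95% interval 4.45 to 5.09), at 108 against 22.7 RPKM, and Id3 was at 17.9 against 2.11 RPKM, while Id1 was higher, at 0.835 against 5.51 RPKM. Of 18 p53 target genes, 1 was at least 2-fold higher, the death receptor gene Fas at 2.36 against 20.4 RPKM, and 4 were lower, including Plk2 (2.82 against 0.358) and Aen (25.1 against 9.06; median 0.01, percentile 57.8). Apoptosis regulators had a median of 0.30 (percentile 97.2, 22 measured; 98 with transcript means, 98.5 with length matching and 98.2 without distal chromosome 2 genes), with Bcl2l1 at 36.6 against 11.3 RPKM. DNA repair genes had a median of -0.20 (percentile 10, 27 measured; 1.25 with the filter at a mean of 5 RPKM), and Xrcc5 was at 10.8 against 3.49 RPKM. Among 22 modifiers of H3K27 and H3K4 (median -0.11, percentile 18.5), the related demethylase gene Kdm6b was lower, at 8.88 against 3.24 RPKM, and Ash2l was at 11.1 against 20.9 RPKM.

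By chromosome, chromosome 2 and the Y stood apart by the size of the difference. The 867 chromosome 2 genes had a relative median of -0.40, below all random lists (percentile 0). In gene order, taken from the GRCm38.p6 RefSeq annotation, the difference was in the distal part: 267 genes up to Stam2 had a median of 0.11 and 583 genes from Fmnl2 onward -0.57, and 85.4% of the distal genes lay below the all-gene median. That point was placed where the parts differed most, after the values were seen. The distal genes held 206 of the 1528 genes at least 2-fold lower; without them 737 genes were higher and 1322 lower. Chromosome 7 had a median of -0.13 (percentile 0, and 8.65 with the filter at a mean of 5 RPKM) and chromosome 8 of 0.15 (percentile 100). Chromosomes 3, 6 and 15 lay above the range of random lists with medians of 0.08, 0.06 and 0.10, but each lay within that range under at least 3 of the alternative settings. The X had a median of 0.05 (percentile 91.2).

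**Figure D3:**
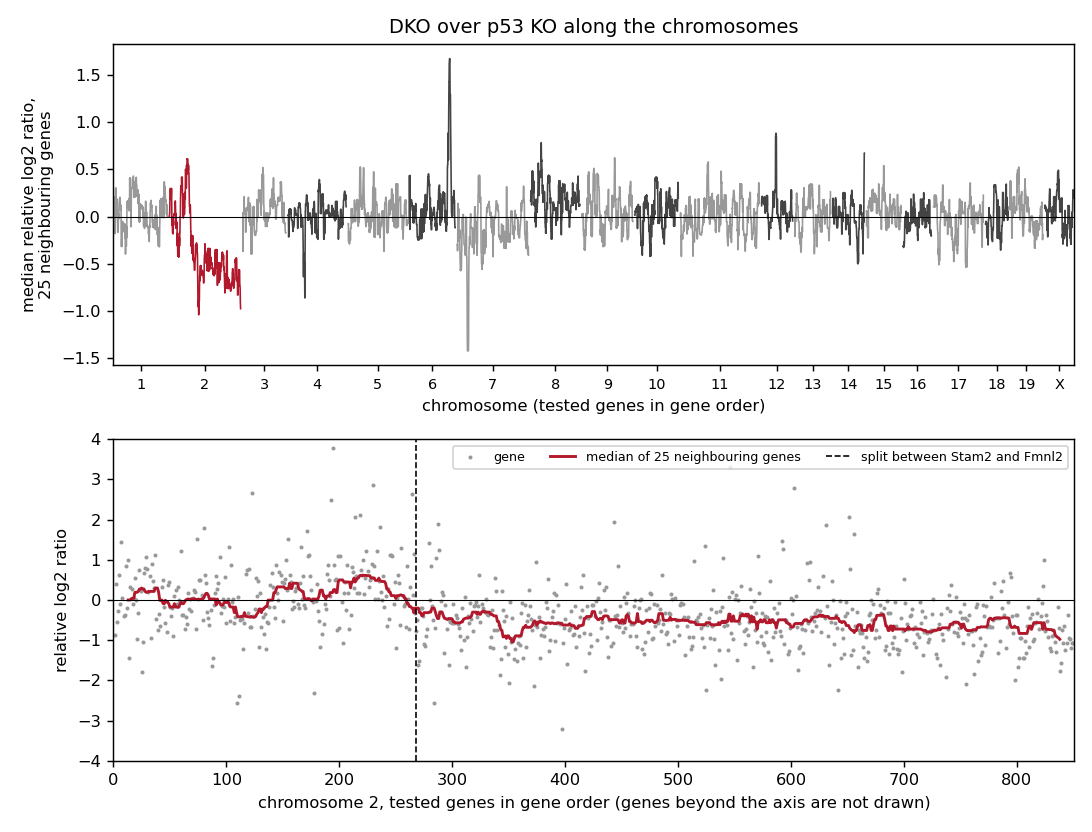
Relative log2 ratio, DKO over p53 KO library, along the chromosomes in gene order: the upper panel shows running medians of 25 neighbouring genes on each chromosome (x axis) and the lower panel every chromosome 2 gene as a point with the running median as a line. From the dashed line between Stam2 and Fmnl2 onward the median of the chromosome 2 genes was -0.57.

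All 4 measured Y-linked genes were lower in the DKO library. Ddx3y was at 25.5 against 4.14, Eif2s3y at 31.6 against 5.91, Kdm5d at 5.24 against 1.25 and Uty, the Y-linked partner of Kdm6a, at 3.18 against 0.365 RPKM. Their RPKM ratios, DKO over p53 KO, were 0.162 (95% interval 0.145 to 0.181), 0.187 (95% interval 0.160 to 0.218), 0.238 (95% interval 0.195 to 0.288) and 0.115 (95% interval 0.0795 to 0.161). The relative median of these genes was -1.69 (percentile 0.02), against -0.08 (percentile 35.2) for their 4 X-linked partners, Kdm6a included. Xist, the RNA of the inactive X of female cells, was low in both libraries, with 86 reads in the p53 KO library and 6 in the DKO library (0.411 against 0.0246 RPKM).

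**Figure D4:**
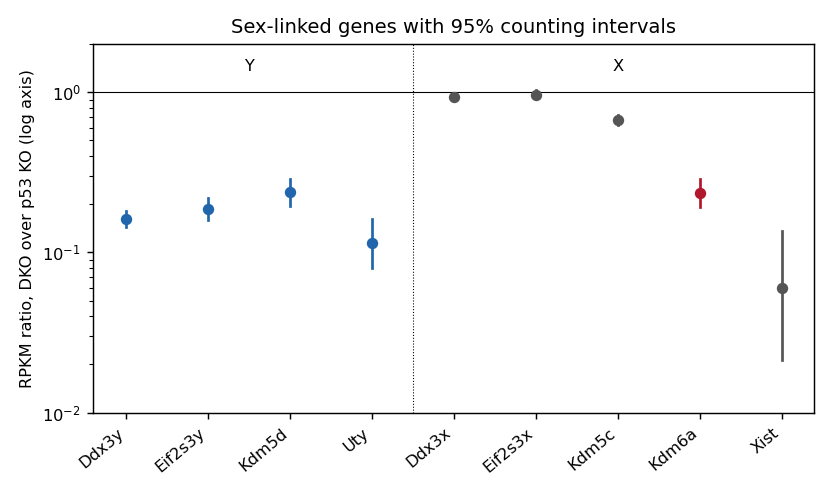
RPKM ratio, DKO over p53 KO library (y axis, log scale), of Y-linked genes, their X-linked partners and Xist (x axis), as points with 95% counting intervals. The Y-linked genes lie between 0.115 and 0.238 and Kdm6a at 0.236, below Ddx3x, Eif2s3x and Kdm5c.

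In the authors' deposited table, which compares the same libraries with gfold, 8901 of 28344 transcripts had a GFOLD value above 0 and 5695 below 0. GFOLD, gfold's own shrunken form of the log2 fold change, was at least 1 for 2174 transcripts and at most -1 for 1579 in the authors' deposited table. The authors' q-value (E-FDR) was 1 for every transcript of that deposited table, so 0 transcripts had a value under 0.05. Being the same for every transcript, with 1 library per genotype, it cannot tell whether any gene differed. Of the 750 genes at least 2-fold higher here, 747 had a GFOLD above 0 in the authors' deposited table, and of the 1528 lower genes 1473 had one below 0. Both measures come from the same reads, so this overlap gives no independent support. The authors' deposited table gave Kdm6a a GFOLD of -1.15 and Trp53 a GFOLD of 0.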

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

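No paired analysis was possible because each genotype has 1 library. The alternatives with gfold constants, transcript means, length matching, near-identical copies and distal chromosome 2 genes were chosen after seeing the data. Of the counts, targeted-gene ratios and percentiles of lists and chromosomes, 632 values under an alternative stayed within their limits, 17 moved beyond them, 9 percentiles passed into the outer range and 20 left it. Of the named genes' ratios, 885 moved by less than the set limit and 212 by more. No ratio of at least 2-fold changed sign, but those of 4 genes under 2-fold did: Trp53 and Kdm5c with the gfold constants, and Ddx3x and Eif2s3x with these, with centring and with upper quartiles. With the gfold constants more genes were higher than lower, the opposite of the main setting. The cause of these changes was not tested, except that a stricter filter leaves fewer genes. Counts of higher and lower genes were 426 and 476 with a pseudocount of 5, 1873 and 712 with the gfold constants, 369 and 493 at 3-fold, and 1481 and 3363 at 1.5-fold; lower genes numbered 835 with a mean of at least 5 RPKM and 3332 with equal totals. The log2 ratio of Kdm6a was -2.00 with a pseudocount of 0.1, -0.72 with 5, -2.09 with equal totals and -1.12 with the gfold constants, and with a mean of at least 5 RPKM Kdm6a left the set. That of Trp53 was -0.37 after centring, -0.94 with equal totals and 0.01501 with the gfold constants.

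Without the filter, Hoxa, Hoxb and cofactor genes lay at percentile 24.3, homing receptors at 13.4 and chromosome 6 at 97.45. With a mean of at least 5 RPKM, mast cell, basophil and eosinophil genes lay at 43.1, homing receptors at 19.1, macrophage and dendritic cell genes at 99.7, DNA repair genes at 1.25, and chromosomes 3, 5, 6, 7 and 15 at 91.6, 99.1, 97.3, 8.65 and 96. Chromosome 6 lay at 96.2 with a pseudocount of 0.1, 97.1 with upper quartiles and 95.3 with the gfold constants. Chromosome 15 lay at 96.8 with a pseudocount of 5, 97.3 with upper quartiles and 91 with the gfold constants, and chromosome 3 at 95.7 and 96.2 with that pseudocount and those constants. With length matching, TNF and NF-kB response genes lay at 2.31, ribosomal protein genes at 93.3, apoptosis regulators at 98.5 and chromosome 1 at 97.7. Ribosomal protein genes lay at 91.5 by their mean, and apoptosis regulators at 98 with transcript means. Without distal chromosome 2 genes, GATA and megakaryocyte-erythroid factors lay at 2.19, homing receptors at 25.4 and apoptosis regulators at 98.2. Chromosome 2 stayed at percentile 0 under each alternative run on chromosomes. The authors' q-value called 0 transcripts at 0.01 as at 0.05, which was fixed because every transcript had the same value. Counts of these calls are among the values that stayed within their limits, and they could not have moved.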

Other observations

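The tests and gene groups in this part were chosen after the result was seen, except the percentile of the sex-linked genes, a list fixed beforehand. Genes of the acute phase and of secreted defence were picked from those with large increases, so that they were higher follows from the choice; besides Hp, C3 and Lcn2, a member of a fixed list, they included the protease inhibitor gene Slpi (127 against 2216 RPKM) and serum amyloid Saa3 (0.882 against 24.3 RPKM). The metallothionein genes Mt1 (25.2 against 389) and Mt2 (1.89 against 30.5), which bind zinc and copper, were higher, and 4 of 7 Gstm glutathione transferase genes were at least 2-fold higher, with Gstm1 at 101 against 843 and Gstm2 at 1.68 against 42.1 RPKM. Of all 21 Klra genes in the table, the Ly49 receptors of NK cells, 19 had a higher RPKM in the DKO library, Klra7 at 1.25 against 19.7 RPKM, and 2 a lower one, Klra10 (0.782 against 0.305) and Klra17 (1.39 against 0.256); most were at a few RPKM or less. Klra and Gstm genes are close copies of each other, so the value of a single member is uncertain.

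Most H2B histone genes and some class II antigen presentation genes were lower. Of 18 measured H2B histone genes, 13 were at least 2-fold lower and 0 higher relative to the all-gene median, with a median of -1.24. How completely the oligo-dT selection captured RNA of these histone genes was not tested, so their values are uncertain. Of 9 class II antigen presentation genes, 4 were lower by that measure, H2-Ob, H2-Oa (15.8 against 2.25 RPKM), H2-Ab1 (140.4 against 35.8 RPKM) and H2-DMa (188 against 69.7 RPKM), and the others differed by less than 2-fold, Cd74 at 352 against 229 RPKM. Reads on genes that blood cells are not known to use were more frequent in the p53 KO library: 37.7% of olfactory and vomeronasal receptor genes had reads there and 8.77% in the DKO library, with means of 0.184 and 0.0258 RPKM. In the table as a whole, 4166 transcripts were at 0 in the p53 KO library and 7688 in the DKO library, although the latter had more reads.

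Distal chromosome 2 genes were lower in the DKO library throughout the segment from Fmnl2 onward. Lists matched on GC content, length and abundance never had a median as low (percentile 0 of 2000 draws, with both values known for 97.3% of the genes), which argues against those properties. The lowest median of as many neighbouring genes on another autosome was -0.14, on chromosome 7. Only autosomes with at least that many ordered genes could be compared, and the stretches compared overlapped. If only a few of the segment's genes were regulated, the upper quartile would stay near that of the other autosomes. It was shifted by -0.66 against them, with shifts of -0.45 at the 10th percentile, -0.60 at the median and -0.82 at the 90th. This argues against a few regulated genes only. A change of cell type that moved many of the genes is not excluded, because the segment was bounded on these same values. A candidate explanation is a copy number difference of the segment between the cells of both libraries. All 11 blocks of 50 neighbouring genes in it were lower, the highest at -0.43, against 1 of 189 blocks elsewhere below -0.4. The segment was bounded on these same values, so low blocks follow in part from that choice and cannot decide for this explanation. If expression followed copy number alone, the same shift would appear across the percentiles, but shifts on log2(RPKM + 1) ran from -0.45 to -0.82. In the segment's 146 genes with a mean of at least 20 RPKM the shift of the log2 RPKM ratio against the other autosomes was -0.72 (95% bootstrap interval over genes -0.82 to -0.62). If expression followed copy number in all cells, 2 copies against 3 would give -0.585 and 1 against 2 would give -1, both outside that interval. Whether expression followed copy number was not tested, and other copy numbers or a change in a part of the cells could give other sizes. The size alone therefore does not tell a change in all cells from one in a part of them, or a loss in the DKO cells from a gain in the p53 KO cells. Nor does it tell the role of the genotype, and no DNA was analysed here.

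Y-linked genes were lower in the DKO library while Ddx3x and Eif2s3x stayed near the all-gene median. Female cells among the DKO cells are argued against by Xist, whose RPKM ratio, DKO over p53 KO, had an upper bound of 0.136. A general difference of genes at that abundance is argued against by the percentile of 0.02 among matched random lists. A lower share of cells with a Y chromosome among the DKO cells cannot be told apart from a change in these genes' expression: the log2 ratios of the 4 genes spanned 1.05, within what 4 random genes of their abundance give (percentile 17.4), and the counting intervals of Uty (0.0795 to 0.161) and Kdm5d (0.195 to 0.288) did not overlap, so 1 common ratio alone does not describe them. Shared regulation of these genes by the deleted demethylase was not tested.

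Granulocyte and monocyte genes were higher and the list of long-term stem cell genes was lower in the DKO library. Mature neutrophils in the sort, which the selection against lineage markers should remove, were considered as a source. The median of 11 genes grouped as mature neutrophil genes, among them the secondary granule gene Ltf, lay -2.41 from that of Mpo, Elane, Prtn3, Ctsg and Ms4a3 on the log2 scale. The abundant S100a8 and S100a9 were at 259 against 1190.4 and 193 against 454 RPKM, compared with 1649 against 26714 RPKM for Elane, which thus rose more. Both groups were formed after the values were seen, and Lcn2, at 59.5 against 704 RPKM, stood in neither. The gap therefore follows in part from the grouping and does not exclude mature neutrophils. All 11 of those mature genes were also at 1 RPKM or more in the p53 KO library, and 10 stand in a fixed list. Immature myeloid cells in the sort cannot be told apart from a change within LSK cells. The reading chosen here took lower levels of both gate genes as a sign of such cells, and unchanged levels as a sign against them. These genes moved apart (relative log2 ratio of Kit -1.70, of Ly6a 0.38). Immature myeloid cells also need not lower both, so the gate genes cannot decide the question. The loss of Utx stays open as an untested biological explanation, since with 1 library per genotype it is confounded with the animal and the sort.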
